A study of Homo sapiens with 6 samples.

How the data were processed

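RNA was measured in 6 samples of the human neuroblastoma line CHP-134, 3 with a control guide RNA and 3 with TRIM24 knocked out, as named by the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq stranded mRNA kit. The deposited table holds FPKM per gene, that is fragments per kilobase of gene and per 1e6 mapped fragments, with 1 column per sample per the file headers. HISAT2, featureCounts and the build hg19 are named in the submitters' processing notes, with no versions or settings. The column names for gene identifier and gene name are those of Cufflinks tables, per the file headers, so which program made the FPKM values is not given in the sources used here, and neither is the annotation release. Strand settings of the counting are not given either, so antisense and overlapping genes cannot be separated with certainty. FPKM are scaled to each library's total, so a change in very abundant genes shifts all others, and genes with near-identical copies can gain or lose fragments to each other.

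The table lists 63129 Ensembl gene identifiers. Current symbols were found for 51653 of them (81.8%) in a reference annotation on GRCh38, and the table's own names were kept for the rest. Because the table was made on hg19, no coordinates are printed. Annotation on GRCh38 served only for symbols, gene types, chromosomes, the order of neighbouring genes, and the transcript counts and exon lengths used to estimate depth. No library's column repeated another's. Levels of sex-linked marker genes on the Y chromosome and of the X-inactivation transcript were left out.

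Before the data were examined, a count-based test was planned, with a stated fallback for a table without counts. As the table holds FPKM, the fallback was used: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), over the 13670 genes with a mean of at least 1 FPKM across all 6 samples. The model held the group with no other term. The two-sided test was adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Changes are knockout minus control on the log2(FPKM + 1) scale, which understates changes of genes with low values, while folds given in the text are ratios of mean FPKM. Genes listed at 0 are given as each library's value, since a 0 in such a table can be a failed estimate.

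Genes were named by a rule fixed before the data were examined. It took TRIM24, MYCN, KDM1A, RCOR1, TRIM28 and TRIM33 in every case. It also took the 10 largest rises and 10 largest falls among called genes with a mean of at least 3 FPKM, an official symbol and groups that did not overlap. From each gene list it took up to 4 called members with a mean of at least 1 FPKM and the largest changes, or, where none was called, the 2 most abundant members. Some genes that the rule names are not reported here. DPYSL3, SATB1, TFAP2A, BHLHE40, LDHA, MDM2, HDAC1, HDAC2, RCOR2, ZMYM2 and INSM1 are named outside that rule and were chosen after their values were seen. In all, 35 gene lists were fixed beforehand, covering lineage, neuronal function, chromatin, signalling, metabolism, stress, cell cycle and markers of other cell types. They hold 895 distinct genes, of which 890 were found and 652 tested. Each list with at least 5 tested members was compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. The same test with an estimated correlation is given beside each list called, and the self-contained test fry is given for the lists where its call differs.

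Depth was estimated for each library, since no totals are given. In genes with a single annotated transcript of at least 1500 nt, low FPKM values were matched to whole multiples of 1 fragment, up to 5, assuming fragments of 200 nt. Of the low values, 86.9% to 89.3% lay within 0.05 of a whole multiple. The estimates run from 26.3 to 36.1 M fragments, so that 3 fragments on 1 kb correspond to 0.0831 to 0.114 FPKM. They cover counting error only and depend on the assumed fragment length. They also depend on exon lengths from the GRCh38 annotation, which may differ from those behind the FPKM values.

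The procedure was tested on simulated data with 13670 genes, 100 genes changed per size and 10 draws. Each gene's spread was taken from the real libraries and was alike for both groups. On average 73.7% of changes of log2 1 and 96.5% of changes of log2 2 were called. Of the calls, 6.47% fell on unchanged genes, and the median absolute error was 0.0779 on the log2 scale. Changed genes were drawn only from the better expressed genes, so the shares called do not cover genes with low values. The real groups differed in spread: control libraries correlated at 0.990 to 0.994 and knockout libraries at 0.960 to 0.986. The draws held neither this difference nor an outlying library. The shares called and the share of calls on unchanged genes may therefore not hold for the real comparison. A list of 30 genes shifted by log2 0.4 passed an unadjusted camera test in 10 of 10 draws and an unshifted list in 0. Noise was drawn independently for each gene, so these draws cannot show how often lists of correlated genes are called falsely. In the real data the correlation estimated for the integrated stress list was 0.944.

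Other settings fixed before the data were examined were median-of-ratios scaling, a pseudocount of 0.1, no filter, a filter of 1 FPKM in at least 3 samples, removal of the 20 most abundant genes, the replicate number as a block, and leaving out each library. Quantile normalization, scaling to TPM, array weights and a minimum mean of 5 FPKM were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.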

Results

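Gene expression was measured in CHP-134 cells, a human neuroblastoma line with MYCN amplification, grown in culture. The design has 2 groups of 3 samples each: cells carrying a control guide RNA and cells in which TRIM24 had been targeted with CRISPR. TRIM24 encodes a chromatin reader and ubiquitin ligase of the TIF1 family. The labels call the samples biological replicates. Polyadenylated RNA was sequenced with a stranded kit, and the deposited values are FPKM per gene. Depth is not stated with the values, so it was estimated from the smallest steps between low FPKM values. These steps gave 32.5, 33.8 and 36.1 M fragments for controls 1 to 3 and 35.3, 26.3 and 30.2 M for knockouts 1 to 3. At those depths, 1 FPKM on a transcript of 2 kb stands for 52.5 to 72.2 fragments. Of 63129 listed genes, 35932 were at 0 in all 6 libraries and 13670 had a mean of at least 1 FPKM and were tested.

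The control libraries lay close together, with Pearson correlations of 0.990 to 0.994 across the tested genes. Knockout 1 and knockout 2 correlated at 0.986, and knockout 3 correlated with them at 0.960 to 0.971. Knockout 3 correlated with the controls at a mean of 0.970, which lies within the range for its own group. These correlations are across genes, which are not independent replicates. The first principal component held 59.6% of the variance and the second held 22.3%.

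**Figure D1:**
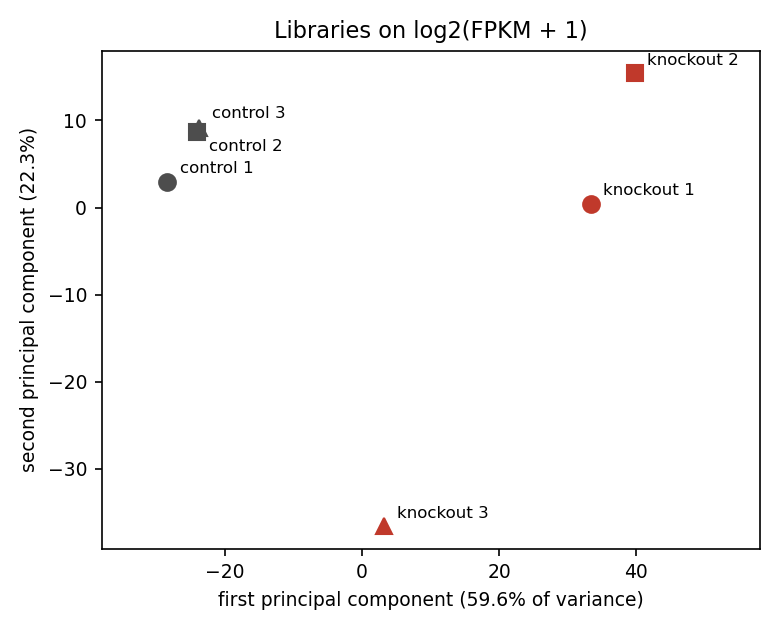
Principal components of log2(FPKM + 1) over the 13670 tested genes, 1 point per library, with the first component (59.6% of variance) on the horizontal axis and the second (22.3%) on the vertical axis. The 3 controls (grey) group together, knockouts 1 and 2 (red) lie at 33.3 and 39.7 on the first component, and knockout 3 lies at 3.22.

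The comparison of knockout with control cells addresses which transcripts differ between the groups, in a study concerned with neuronal differentiation and the LSD1/CoREST corepressor. The sample titles do not say whether the knockouts come from separate guides or clones. A difference between the cells used therefore cannot be told apart from an effect of TRIM24 loss. TRIM24 itself (ENSG00000122779, chromosome 7) stood at 34.5, 35.2 and 34.6 FPKM in the controls and at 9.36, 9.93 and 6.45 FPKM in the knockouts, which is 24.7% of the control mean. Of the genes of the neuronal cytoskeleton 7 of 29 rose, DCX among them, and 1 fell, and of synaptic vesicle genes 8 of 24 rose, SV2B among them, and 1 fell. The adrenergic transcription factors PHOX2A and GATA2 and the cell cycle inhibitor CDKN1A also rose. The neuropeptide gene NPY, the calcium-binding protein gene S100A6 and the transcriptional co-regulator CITED1 fell. Of the hypoxia and glycolysis genes 7 of 31 fell, BNIP3 and PDK1 among them, and 2 rose. None of these 3 lists passed with an estimated correlation (limma camera adjusted p = 0.378 to 0.448).

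TRIM24 fell by 1.92 on the log2(FPKM + 1) scale (SE 0.15, limma adjusted p = 0.000713, n = 3 per group). MYCN, the amplified driver gene of this line, was at 865 ± 8.95 FPKM in controls and 806 ± 16.6 in knockouts (SD, n = 3; limma adjusted p = 0.505). KDM1A, which encodes LSD1, was at 342 ± 13.5 and 307 ± 2.58 FPKM, and its CoREST partner RCOR1 was at 11.3 ± 0.647 and 8.98 ± 0.851 FPKM. Neither passed the main test (limma adjusted p = 0.305 and 0.134). RCOR1 passed without knockout 3 (limma adjusted p = 0.0290), and both passed with array weights (limma adjusted p = 0.0230 and 0.00307). The fit with array weights called 8325 of 13670 genes. It rests largely on knockout 1, weighted 6.83 against 0.262 and 0.116 for knockouts 2 and 3. The related TIF1 genes also did not pass the main test: TRIM28 was at 248 ± 6.04 and 289 ± 36.3 FPKM and TRIM33 at 16.1 ± 0.584 and 13.0 ± 1.55 FPKM (limma adjusted p = 0.266 and 0.148). TRIM33 did pass without knockout 3 and with array weights (limma adjusted p = 0.0175 and 0.00169).

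**Figure D2:**
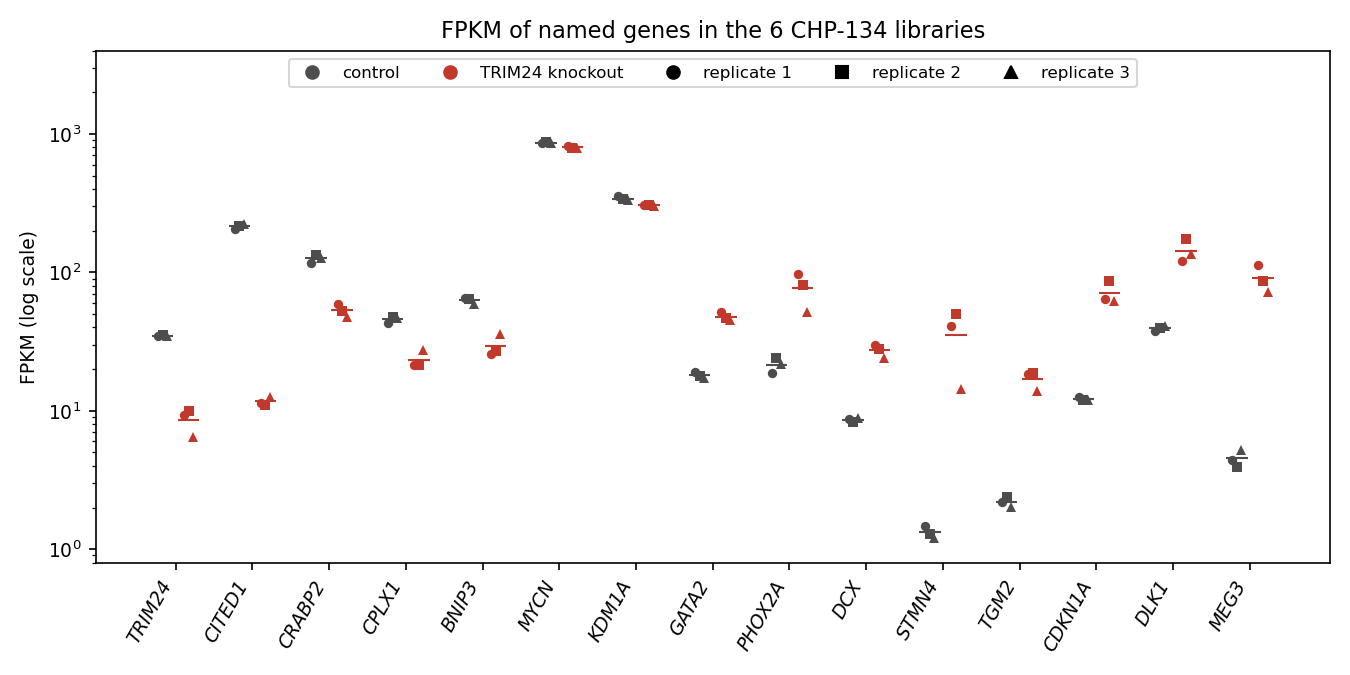
FPKM on a log scale for 15 genes in each of the 6 libraries, with controls in grey, knockouts in red, marker shape for the replicate and a horizontal bar at each group mean. TRIM24 lies at 34.5 to 35.2 FPKM in controls and at 6.45 to 9.93 in knockouts, while MYCN lies at 856 to 874 FPKM in controls and at 794 to 825 in knockouts.

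In all, 1189 of 13670 genes differed at a limma adjusted p under 0.05, which is 8.70% of the genes tested. Of these, 681 were higher and 508 lower in the knockouts. With an absolute log2 change of at least 1 as well, 272 were higher and 128 lower. The groups did not overlap for 4573 genes, or 33.5%, against a chance share of 10% for 3 libraries against 3. Without knockout 3, 4928 genes passed (2472 higher and 2456 lower), and all 1189 genes were among them. Leaving out a control instead left 378 to 400 genes, and leaving out knockout 1 left 526. Each such fit has fewer samples, so a call lost in it, here and below, need not rest on the library left out. A minimum mean of 5 FPKM, with 9821 genes tested, left 769, and the replicate number as a block left 653. Array weights, at 6.83, 0.262 and 0.116 for knockouts 1 to 3, gave 8325.

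Among the largest rises were MEG3, an imprinted long noncoding RNA, which rose from 4.52 ± 0.642 to 91.0 ± 21.3 FPKM (SD, n = 3), and the neuronal microtubule regulator STMN4, from 1.32 ± 0.130 to 35.3 ± 18.7 FPKM. SYNPO2, which binds actin, rose 16.2-fold, the fatty acid carrier gene FABP3 21.8-fold and the orphan receptor gene GPR50 24.2-fold. IGFBP5, a secreted binder of insulin-like growth factors, rose 10.4-fold, to 73.3 ± 25.8 FPKM. The interferon-inducible GTPase gene GBP2 stood at 8.67, 9.45 and 8.94 FPKM in controls and at 252, 441 and 38.1 in knockouts. The cancer-testis genes PAGE1 and GAGE12H rose 42.6-fold and 9.56-fold, but near-identical copies on the X chromosome make their values uncertain. The same holds for GSTM1, a glutathione transferase of a gene cluster, listed at 0.0489, 0 and 0 FPKM in controls and at 12.4, 11.1 and 14.9 in knockouts. All 10 of these rises had a limma adjusted p between 1.83e-05 and 0.0215. The call of GBP2 ended without any of the 3 controls, without knockout 1 and with no filter on low values (highest limma adjusted p = 0.0994), and the other 9 calls held with each library left out.

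The largest falls took several genes close to 0. GTSF1, a factor of the piRNA pathway, stood at 46.2, 44.4 and 45.9 FPKM in controls and at 0.125, 0 and 0 in knockouts. NPY was at 7.06, 6.46 and 6.95 FPKM in controls and was listed at 0 in every knockout. TCEAL5 went from 7.99, 8.44 and 8.87 to 0.0298, 0 and 0 FPKM. ANKRD30A went from 6.76, 7.14 and 7.08 to 0.0133, 0.00900 and 0 FPKM, and MCF2, a guanine nucleotide exchange factor gene, from 6.94, 7.47 and 6.79 to 0.0658, 0 and 0.0580 FPKM. ANKRD30A overlaps noncoding genes, so its value is uncertain. S100A6 fell from 39.9 ± 1.73 to 0.157 ± 0.0914 FPKM and RCN1, a calcium-binding protein of the endoplasmic reticulum, from 9.25 ± 0.241 to 0.332 ± 0.123 FPKM (SD, n = 3). CITED1 fell from 215 ± 8.07 to 11.7 ± 0.842 FPKM, CHRNA9, a nicotinic receptor subunit, from 18.9 ± 0.699 to 0.935 ± 0.372 FPKM, and BEX2 from 68.2 ± 3.84 to 6.98 ± 4.51 FPKM. For these 10 falls the limma adjusted p lay between 1.15e-06 and 0.00475, and each held with every library left out in turn.

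Gene lists fixed before the data were examined were compared with all other tested genes by camera in limma. With a preset correlation between genes of 0.01, 14 of the 32 lists with enough tested members passed at an adjusted p under 0.05, and 0 did with the correlation estimated for each list, where the limma camera adjusted p ran from 0.378 to 0.971 over the 32 lists. The number called was 9 under median-of-ratios scaling or without the 20 most abundant genes, and 7 without control 1 or knockout 1. At an unadjusted p under 0.05, 17 lists passed with the preset value and 1, the neurite list, with the estimated one. The self-contained test fry, which asks whether a list moves on balance 1 way and compares it with no other genes, called 11 lists, which were not the same set. Of the 14 lists called by camera, fry called 7: the neurite, adrenergic, axon guidance, p53, hypoxia and glycolysis, LSD1/CoREST and histone lists (limma fry adjusted p = 0.00747 to 0.0305). It did not call the synaptic (limma fry adjusted p = 0.0653), immediate early (0.142), respiratory chain (0.205), MYC and MYCN (0.217), unfolded protein (0.234), integrated stress (0.611) and noradrenergic (0.900) lists. It called 4 lists that camera did not: the glial list (limma fry adjusted p = 0.000923) and the TIF1 family list (0.00128), both downward, and the BCL2 family (0.00205) and retinoic acid lists (0.0297), both upward. The TIF1 family list holds TRIM24, the targeted gene and its only called member, so that result is not independent of the knockout. The counts of members below are over all genes tested, and beside them stand the counts adjusted over the list alone.

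Among neurite and neuronal cytoskeleton genes 7 of 29 rose, 1 fell and 21 were not called, with a median log2 change of 0.33 (limma camera adjusted p = 1.17e-05, and adjusted p = 0.378 with an estimated correlation). The counts adjusted over the list alone were 15 higher and 1 lower, and without knockout 3 the counts over all genes were 18 and 2. DCX, which binds microtubules in migrating neurons, rose from 8.64 ± 0.294 to 27.4 ± 2.98 FPKM (SD, n = 3). The adhesion genes CNTN2 and CNTN1 rose 2.15-fold and 2.13-fold. STMN4 rose most in this list, and DPYSL3 fell by 0.72 on the log2 scale.

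Synaptic vesicle and release genes had 8 of 24 tested members higher, 1 lower and 15 not called (median log2 change 0.32, limma camera adjusted p = 0.00137, and adjusted p = 0.448 with an estimated correlation), or 9 higher and 1 lower adjusted over the list alone. The vesicle genes SYNGR3 and SV2B rose 3.92-fold and 3.08-fold. SYN1, a synapsin, rose 2.89-fold, but its call ended without any control or without knockout 1 (highest limma adjusted p = 0.0945). CPLX1, a complexin that acts on vesicle fusion, fell from 45.7 ± 2.17 to 23.4 ± 3.52 FPKM (SD, n = 3). The median change of this list was 0.50 in knockout 1, 0.61 in knockout 2 and 0.01 in knockout 3, and without knockout 3, 14 members were higher and 1 lower.

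Adrenergic transcription factors, the core regulators of the sympathetic state of neuroblastoma, included 5 of 21 that rose, 2 that fell and 14 not called (median log2 change 0.28, limma camera adjusted p = 0.0169, and adjusted p = 0.448 with an estimated correlation). Adjusted over the list alone, 11 rose and 3 fell. GATA2 rose from 18.1 ± 0.853 to 47.9 ± 3.23 FPKM, PHOX2A from 21.5 ± 2.67 to 76.9 ± 23.2 FPKM and ZNF536 from 0.320 ± 0.0381 to 4.37 ± 1.35 FPKM (SD, n = 3). TBX2 rose 3.06-fold, with its call lost without any control or knockout 1 (highest limma adjusted p = 0.0881). SATB1 and TFAP2A fell by 1.10 and 0.68 on the log2 scale. Without knockout 3, 10 members were higher and 3 lower. The list's call ended without knockout 1 and with a minimum mean of 5 FPKM (limma camera adjusted p = 0.110 and 0.0532).

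Noradrenergic synthesis and storage genes went both ways. Of 15 tested members 4 rose, 1 fell and 10 were not called, and adjusted over the list alone 7 rose and 2 fell. The median log2 change was 0.32 and the mean 0.17 (limma camera adjusted p = 0.0474, upward, and adjusted p = 0.378 with an estimated correlation). The fry test pointed downward (limma fry adjusted p = 0.900). DDC, which makes dopamine from L-DOPA, rose from 0.257 ± 0.140 to 2.21 ± 0.243 FPKM (SD, n = 3), and the granin SCG2 and the peptide-processing enzyme gene CPE rose 3.72-fold and 1.38-fold. NPY was the member that fell. The calls of SCG2 and CPE ended without any control or knockout 1, and that of SCG2 also without knockout 2 (highest limma adjusted p = 0.140 and 0.126). The list's own call ended without control 1, knockout 1 or knockout 3 (highest limma camera adjusted p = 0.113). It was also lost under median-of-ratios, quantile and TPM scaling, without the 20 most abundant genes and with array weights (limma camera adjusted p = 0.0518 to 0.0561).

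Axon guidance and adhesion genes had 5 members higher, 1 lower and 15 not called of 21 (median log2 change 0.07, limma camera adjusted p = 0.0486, and adjusted p = 0.448 with an estimated correlation). By counts adjusted over the list alone, 7 rose and 2 fell. The guidance receptor genes UNC5C and ROBO2 rose 7.39-fold and 4.92-fold and the adhesion gene CADM1 2.10-fold. The cadherin gene CDH7 fell by 1.11 on the log2 scale, a call lost without any control or knockout 1 (highest limma adjusted p = 0.0909). The list passed in only 1 of the 6 fits that left out a library, the one without knockout 2 (highest limma camera adjusted p = 0.210). Its call also ended under median-of-ratios and quantile scaling, without the 20 most abundant genes, with array weights and with the replicate block (limma camera adjusted p = 0.0548 to 0.0687).

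p53 target genes shifted upward as a list, with 2 of 26 higher, 0 lower and 24 not called (median log2 change 0.23, limma camera adjusted p = 0.0301, and adjusted p = 0.378 with an estimated correlation), or 2 higher and 1 lower adjusted over the list alone. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 12.2 ± 0.345 to 70.7 ± 13.3 FPKM (SD, n = 3). PHLDA3 rose 2.47-fold, a call lost without any control or knockout 1 (highest limma adjusted p = 0.105). MDM2, another target, was at 23.6 FPKM in controls and 19.5 in knockouts (limma adjusted p = 0.208). Without knockout 3, 9 members were higher and 2 lower and the list's call ended (limma camera adjusted p = 0.0676), as it did with array weights (limma camera adjusted p = 0.0561).

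Immediate early and MAPK feedback genes had 3 of 17 higher, 0 lower and 14 not called (median log2 change 0.13, limma camera adjusted p = 0.0292, and adjusted p = 0.519 with an estimated correlation), or 6 higher and 0 lower adjusted over the list alone. DUSP4, a phosphatase of MAP kinases, rose 15.1-fold from 0.790 ± 0.0966 FPKM, the synaptic activity gene ARC from 1.22 ± 0.337 to 6.18 ± 2.46 FPKM and JUN from 23.6 ± 3.73 to 68.9 ± 24.3 FPKM (SD, n = 3). Each of these 3 calls was lost without control 1, control 2 or knockout 1, those of DUSP4 and JUN also without control 3 and that of JUN also without knockout 2 (highest limma adjusted p = 0.0791, 0.0709 and 0.101). The list's call ended without control 1 or knockout 1 (highest limma camera adjusted p = 0.157), and without knockout 3, 8 members were higher and 1 lower. Replication-dependent histone genes were 2 of 7 higher, 0 lower and 5 not called (median log2 change 1.05, limma camera adjusted p = 0.0144, and adjusted p = 0.378 with an estimated correlation), with 4 higher and 0 lower adjusted over the list alone. H2BC12 rose 2.34-fold and H2BC5 6.88-fold. H2BC5 passed only without knockout 3 among the fits with a library left out (highest limma adjusted p = 0.142), where 5 of the 7 genes were higher. Histone messages of this class mostly lack a poly(A) tail, so a poly(A) library samples them in part, and near-identical copies make their values uncertain.

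Among hypoxia and glycolysis genes 7 of 31 fell, 2 rose and 22 were not called, with a median log2 change of -0.34 (limma camera adjusted p = 0.00290, and adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone, 13 fell and 3 rose. BNIP3, a mitophagy receptor, fell from 62.9 ± 3.38 to 29.5 ± 5.44 FPKM, the collagen prolyl hydroxylase subunit P4HA1 from 10.6 ± 0.0893 to 4.26 ± 0.975 FPKM and the kinase PDK1, which holds back pyruvate oxidation, from 9.80 ± 0.458 to 4.42 ± 0.626 FPKM (SD, n = 3). EGLN3 rose 2.80-fold and BHLHE40 rose by 0.75 on the log2 scale, and the call of EGLN3 held only without knockout 3 among the fits with a library left out (highest limma adjusted p = 0.160). Without knockout 3, 17 members were lower and 5 higher. The glycolytic enzyme gene LDHA was at 1003 FPKM in controls and 495 in knockouts and did not pass (limma adjusted p = 0.103).

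MYC and MYCN target genes shifted slightly downward, with 2 of 35 lower, 0 higher and 33 not called (median log2 change -0.15, limma camera adjusted p = 0.0474, and adjusted p = 0.680 with an estimated correlation), or 4 lower and 0 higher adjusted over the list alone. PTMA fell 1.57-fold and the nucleolar gene NPM1 from 2540 ± 50.6 to 1690 ± 210 FPKM (SD, n = 3), calls lost without any control, and for NPM1 also without knockout 1 (highest limma adjusted p = 0.0873 and 0.150). The list's call ended without control 1, control 2 or knockout 1 (highest limma camera adjusted p = 0.316), and under median-of-ratios and quantile scaling and without the 20 most abundant genes (limma camera adjusted p = 0.0503 to 0.0692). Their median change was -0.33 in knockout 1, -0.15 in knockout 2 and -0.02 in knockout 3, and without knockout 3, 16 members were lower and 2 higher (limma camera adjusted p = 0.00149). Nuclear genes of the respiratory chain had 1 of 35 lower, 0 higher and 34 not called (median log2 change -0.15, limma camera adjusted p = 0.0169, and adjusted p = 0.680 with an estimated correlation), and 0 in either direction adjusted over the list alone. UQCRC2, a subunit of complex III, fell 1.29-fold, a call kept only without knockout 3 (highest limma adjusted p = 0.179), and the list's call ended without knockout 1 (limma camera adjusted p = 0.168). Their median change was -0.28, -0.12 and -0.04 in knockouts 1 to 3, and without knockout 3, 15 members were lower and 0 higher (limma camera adjusted p = 0.000375).

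The LSD1/CoREST list of 15 tested genes included 1 that fell, 0 that rose and 14 not called (median log2 change -0.15, limma camera adjusted p = 0.0486, and adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone, 3 fell and 1 rose. The gene that fell was REST, a repressor of neuronal genes that recruits CoREST, at 7.15, 7.75 and 7.70 FPKM in controls and 3.27, 1.47 and 3.94 in knockouts (log2 change -1.19, SE 0.25, limma adjusted p = 0.0268). That call ended without any control or knockout 1 and with no filter on low values (highest limma adjusted p = 0.111), and the list's call ended without control 1, control 2 or knockout 3 (highest limma camera adjusted p = 0.298), with 6 members lower and 1 higher in the fit without knockout 3. It also ended under every other scaling and filter of low values tried and with array weights (limma camera adjusted p = 0.0517 to 0.190). HDAC2 was at 250 FPKM in controls and 227 in knockouts, and RCOR2 at 177 and 155 (limma adjusted p = 0.342 and 0.556). HDAC1, ZMYM2 and INSM1 changed more, by -0.51, -0.48 and 1.05 on the log2 scale, and did not pass (limma adjusted p = 0.0627, 0.0625 and 0.0609).

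Integrated stress response and amino acid supply genes had 0 of 35 called in either direction, also adjusted over the list alone, although the list passed (median log2 change 0.33, limma camera adjusted p = 0.0151, and adjusted p = 0.764 with an estimated correlation). Knockout 3 went the other way from its group here: the median change was 0.64 in knockout 1, 0.90 in knockout 2 and -0.46 in knockout 3. In knockouts 1 and 2, 32 of the 35 genes were above all controls, and in knockout 3, 26 were below all of them. ASNS, which makes asparagine, was at 170, 222 and 280 FPKM in controls and at 446, 499 and 98.7 in knockouts, and the stress regulator ATF4 was at 308, 408 and 453 and at 575, 637 and 249 FPKM (limma adjusted p = 0.738 and 0.719, and 0.00172 and 0.00572 with array weights). Without knockout 3, 29 of the 35 genes rose and 0 fell (limma camera adjusted p = 1.92e-10), and the list's call ended without control 1, knockout 1 or knockout 2 (highest limma camera adjusted p = 0.278). Unfolded protein response genes had 0 of 20 called, and 0 adjusted over the list alone (median log2 change 0.22, limma camera adjusted p = 0.0474, and adjusted p = 0.448 with an estimated correlation). Their median change was 0.30 in knockout 3 and 0.00 in knockouts 1 and 2, and the list's call ended without control 1 or knockout 3 (highest limma camera adjusted p = 0.336), with 7 members higher and 2 lower in the fit without knockout 3. Median-of-ratios scaling, removal of the 20 most abundant genes and array weights ended it too (limma camera adjusted p = 0.0506 to 0.344). The chaperone gene CALR was at 348 ± 32.7 and 359 ± 38.6 FPKM (SD, n = 3), and SEC61B was at 172 ± 5.42 and 188 ± 33.4.

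**Figure D3:**
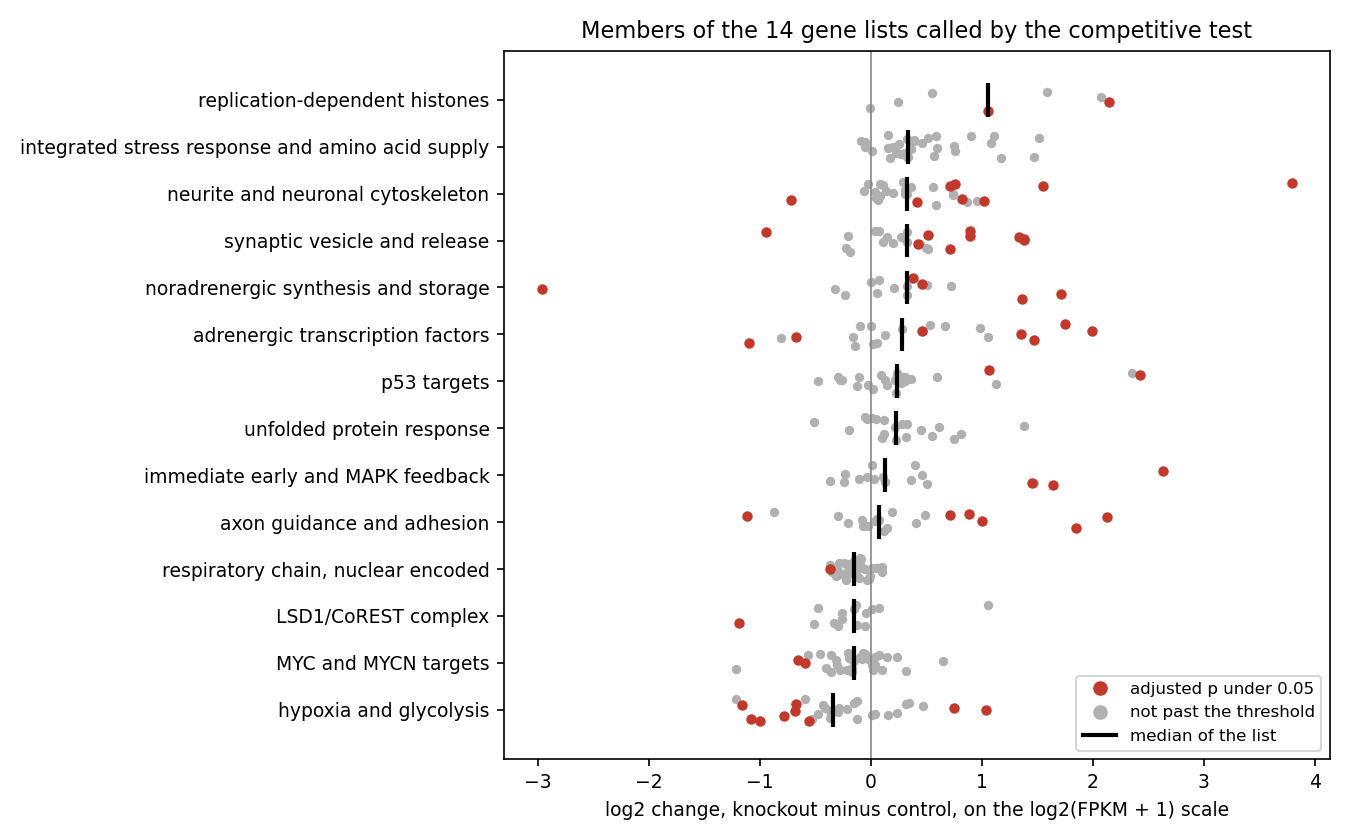
Log2 change of each member of the 14 lists called by camera with the preset correlation, knockout minus control on the log2(FPKM + 1) scale on the horizontal axis, with 1 row per list. Red points passed a limma adjusted p of 0.05, grey points did not, and black bars mark list medians, which run from 1.05 for the histone genes to -0.34 for the hypoxia and glycolysis genes. 0 of these lists passed with an estimated correlation.

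For G2/M and mitosis genes, 0 of 35 were called, also adjusted over the list alone (median log2 change -0.25, limma camera adjusted p = 0.0608). TOP2A was at 226, 196 and 192 FPKM in controls and at 113, 100 and 209 in knockouts, and UBE2C at 261, 233 and 221 and at 152, 213 and 298 FPKM (limma adjusted p = 0.183 and 0.691, and 4.11e-05 and 0.000581 with array weights). The median change was -0.57 in knockout 1, -0.29 in knockout 2 and 0.24 in knockout 3. Without knockout 3, 20 of the 35 fell and 0 rose (limma camera adjusted p = 1.82e-06), and the list also passed without control 2 or control 3 (limma camera adjusted p = 0.0415 and 0.0170). With all 6 libraries it passed without a filter, with the replicate block and with array weights (limma camera adjusted p = 0.0391, 0.0494 and 3.79e-07). S phase and DNA replication genes had 1 of 39 higher and 0 lower (median log2 change -0.11, limma camera adjusted p = 0.307), with 0 in either direction adjusted over the list alone. The gene that rose was GINS3, from 17.4 ± 1.10 to 26.0 ± 3.87 FPKM (SD, n = 3), a call lost without any control or knockout 1 (highest limma adjusted p = 0.171). The median change of this list was -0.20 in knockout 1, -0.23 in knockout 2 and 0.17 in knockout 3, and without knockout 3 it passed downward, with 13 members lower and 4 higher (limma camera adjusted p = 0.00638).

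Retinoic acid response genes went both ways, with 4 of 15 higher, 2 lower and 9 not called (limma camera adjusted p = 0.128), and 5 higher and 3 lower adjusted over the list alone. The transglutaminase gene TGM2 and the retinol transporter gene STRA6 rose 7.76-fold and 2.82-fold, and CRABP2, a carrier of retinoic acid, fell from 126 ± 8.29 to 53.3 ± 5.59 FPKM (SD, n = 3). MEIS1 rose 1.72-fold, a call lost without any control or knockout 1 (highest limma adjusted p = 0.163). Neurotrophin and RET receptor genes had 3 of 10 higher and 1 lower (limma camera adjusted p = 0.136), and 5 higher and 1 lower adjusted over the list alone. This list passed without knockout 2 and with a minimum mean of 5 FPKM (limma camera adjusted p = 0.0486 and 0.0343). The receptor tyrosine kinase gene ALK rose from 3.53 ± 0.101 to 8.37 ± 1.14 FPKM. SORCS1 and VGF rose 2.05-fold and 2.69-fold and NTRK3 fell 1.59-fold, and each of these calls ended without control 1 or control 3, those of VGF and NTRK3 also without control 2, knockout 1 or knockout 2 (highest limma adjusted p = 0.0753, 0.167 and 0.135). Voltage-gated ion channel genes had 2 of 21 higher and 1 lower (limma camera adjusted p = 0.232), and 3 higher and 1 lower adjusted over the list alone. The potassium channel gene KCNMA1 rose 3.39-fold. KCNH2 fell 1.46-fold, a call lost without any control or knockout 1 (highest limma adjusted p = 0.133).

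Mesenchymal transcription factors had 3 of 20 higher, 0 lower and 17 not called (limma camera adjusted p = 0.851), and 5 higher and 6 lower adjusted over the list alone. Their median log2 change was -0.16 while the mean was 0.12 and the test pointed upward. SNAI2 rose 4.22-fold from 0.658 ± 0.199 FPKM (SD, n = 3). NR3C1, the glucocorticoid receptor gene, rose 3.45-fold, and its call and that of JUN held only without knockout 3 among the fits with a library left out (highest limma adjusted p = 0.0818 and 0.101). Notch signalling genes had 3 of 12 higher and 0 lower, and the same counts adjusted over the list alone (limma camera adjusted p = 0.0876). DLK1, an imprinted Notch ligand, rose from 39.5 ± 1.58 to 143 ± 27.6 FPKM. HES4 and NOTCH1 rose 3.37-fold and 3.59-fold, calls lost without control 1 or control 2, for HES4 also without knockout 1 and for NOTCH1 also without control 3 (highest limma adjusted p = 0.0764 and 0.0629). TGF-beta and SMAD genes had 1 of 15 higher and 1 lower, as they had adjusted over the list alone (limma camera adjusted p = 0.162). BMP7 rose 9.21-fold, a call lost without control 1 or knockout 1 (highest limma adjusted p = 0.0569), and the inhibitory SMAD7 fell 1.89-fold. WNT signalling genes had 3 of 19 higher and 1 lower, and the same counts adjusted over the list alone (limma camera adjusted p = 0.809, upward, against a median log2 change of -0.09). The WNT antagonist genes DKK1 and DKK3 rose 4.24-fold and 1.51-fold, SP5 rose 3.09-fold and LGR4 fell 1.35-fold. None of these 4 calls held without control 1, control 2 or knockout 1 (highest limma adjusted p = 0.199).

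The remaining lists of cell functions had few calls. Interferon response genes had 1 of 14 higher and 0 lower (limma camera adjusted p = 0.319), and 3 higher adjusted over the list alone. The gene was ISG20, 7.01-fold, a call kept only without knockout 3 (highest limma adjusted p = 0.132). In the antigen processing and MHC class I list 0 of 11 were called, also adjusted over the list alone (limma camera adjusted p = 0.959), and CANX was at 201 ± 8.42 and 194 ± 9.05 FPKM (SD, n = 3). For cholesterol synthesis 1 of 24 rose and 0 fell, and the same adjusted over the list alone (limma camera adjusted p = 0.746). This was STARD4, 1.37-fold, a call lost without any control or knockout 1 (highest limma adjusted p = 0.162). In knockout 3, 20 of these 24 genes were below all controls. Without knockout 2 the cholesterol list passed downward, at a median log2 change of -0.26 (limma camera adjusted p = 0.0156), and without knockout 3, 6 members were higher and 0 lower (limma camera adjusted p = 0.0800). Ribosomal protein genes had 0 of 38 called, also adjusted over the list alone (limma camera adjusted p = 0.216). In knockout 3, 36 of the 38 were below all controls, at a median change of -0.33, against -0.08 in knockout 1 and 0.21 in knockout 2, and without knockout 2 the list passed downward (limma camera adjusted p = 0.000187). BCL2 family and apoptosis genes had 1 of 19 higher and 0 lower, and the same adjusted over the list alone (limma camera adjusted p = 0.0682, and 0.0457 without knockout 2). HOX cluster genes had 1 of 11 lower and 0 higher, and the same adjusted over the list alone (limma camera adjusted p = 0.729, and 0.0430, downward, with no filter on low values). HOXA7 fell 1.55-fold, a call lost without any control or knockout 1 (highest limma adjusted p = 0.115). The TIF1 family list had 1 of 10 lower, TRIM24 itself, and 2 lower adjusted over the list alone (limma camera adjusted p = 0.135).

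Markers of other cell types that a neuroblastoma culture could hold were mostly low. Of the Schwann cell precursor and glial markers 5 were tested, 1 fell and 0 rose, and adjusted over the list alone 2 fell and 1 rose (limma camera adjusted p = 0.216). FABP7 fell from 4.74 ± 0.0402 to 0.438 ± 0.181 FPKM (SD, n = 3). Fibroblast and extracellular matrix markers had 4 of 17 higher and 1 lower, and 7 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.162). PDGFRA was at 0.686 ± 0.256 FPKM in controls and 2.93 ± 0.836 in knockouts, TIMP3 rose 1.83-fold and S100A4 from 5.84 ± 0.732 to 11.7 ± 2.98 FPKM, while TIMP1 fell from 3.32 ± 0.346 to 0.610 ± 0.324 FPKM. The calls of PDGFRA, TIMP3 and S100A4 were lost without control 1 or control 3, those of TIMP3 and S100A4 also without control 2 and that of S100A4 also without knockout 1 (highest limma adjusted p = 0.0569, 0.0650 and 0.125). The adrenal cortex and endothelial lists had only 2 tested members each, too few for a list test. DLK1 and FDX1 rose in the former, and CLDN5 rose 2.55-fold in the latter, with the same counts adjusted over the list alone. FDX1 rose 1.76-fold, a call lost without control 2 (limma adjusted p = 0.0553). All 15 mitochondrially encoded genes were listed at 0 in every library and were not tested.

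Other settings ended further calls of genes named above. With no filter on low values, where 27197 genes were tested, these were TBX2, JUN, NR3C1, SCG2, SYN1, VGF, NTRK3, MEIS1, LGR4, CDH7, PTMA, NPM1, GINS3, PHLDA3, ISG20, EGLN3, HES4, SP5, DKK3, DUSP4, ARC, S100A4 and H2BC5 (limma adjusted p = 0.0507 to 0.119). The calls of LGR4, NTRK3, MEIS1, NPM1, GINS3, EGLN3, SP5, UQCRC2, STARD4 and HOXA7 each ended under at least 1 other scaling or without the 20 most abundant genes (limma adjusted p = 0.0504 to 0.105). With the replicate block the calls of SCG2, CPE, VGF, NTRK3, MEIS1, KCNH2, PTMA, NPM1 and GINS3 ended (limma adjusted p = 0.0517 to 0.101). So did those of EGLN3, STARD4, UQCRC2, HES4, SP5, DKK3, LGR4 and HOXA7 (limma adjusted p = 0.0514 to 0.114).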

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

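Quantile normalization, TPM scaling, array weights and a minimum mean of 5 FPKM were chosen only after the results were seen. The planned DESeq2 and voom fits and the fit with library totals alone were not run, because the table holds no counts. TRIM24 stayed lower and past the threshold under every alternative run, between -2.03 and -1.75. The main count of 1189 genes lay between 947 and 1303 under median-of-ratios scaling, a pseudocount of 0.1, both other filters of low values that were planned, removal of the 20 most abundant genes, quantile normalization and TPM scaling, and these scalings moved the median change of all genes by at most 0.02. Of the 1189 calls, 681 were kept without a filter, 956 under TPM scaling, 1019 without the 20 most abundant genes and 1131 to 1188 in the others. The share of calls that were higher was 57.3% in the main fit, 66.3% without the 20 most abundant genes and 65.6% under TPM scaling. A minimum of 5 FPKM, which tests fewer genes (9821), gave 769 (437 higher, 332 lower; 148 and 75 with a log2 change of at least 1). Array weights gave 8325 genes (3894 higher and 4431 lower, or 423 and 194 with a log2 change of at least 1). That fit rests largely on knockout 1, by the weights given above, and whether this alone accounts for the count was not tested. With the replicate block 653 genes passed (405 higher, 248 lower), 643 of them shared with the 1189. The sample titles do not say whether the replicate numbers pair the cultures. The deviations of libraries with the same number correlated at -0.11, 0.12 and -0.13, and not every library correlated best with its own number. Such deviations sum to 0 within each small group, so these values cannot exclude a pairing. Leaving out 1 library, with fewer samples in the fit, gave 378 (without control 2) to 4928 genes (without knockout 3), 230 to 2472 higher and 139 to 2456 lower, and 172 to 475 higher and 94 to 193 lower with a log2 change of at least 1. In those 6 fits 50 of the 88 named called genes kept their call in all, and 0 changed sign. The 14 called lists became 9 under median-of-ratios scaling, 9 without the 20 most abundant genes, 0 with an estimated correlation, and 7 (without control 1 or knockout 1) to 17 (without knockout 2) on leaving out a library, and 4 of them were called in all 6 such fits. With the replicate block the axon guidance list was lost (limma camera adjusted p = 0.0687) and the G2/M list passed (0.0494). The median of the HOX list went to -0.041 without a filter (limma camera adjusted p = 0.0430), that of the cholesterol list ran from -0.26 without knockout 2 (limma camera adjusted p = 0.0156) to 0.18 without knockout 3, and the noradrenergic list, with a median of 0.32, turned downward by fry (limma adjusted p = 0.900). The cause of these was not tested. At the estimated depths, values under about 0.0831 to 0.114 FPKM on 1 kb rest on fewer than 3 fragments.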

Other observations

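The tests of control admixture, of the depth of knockout 3 and of reported REST targets, and the quantile normalization used below, were chosen only after the results they bear on were seen, and the genes named here were likewise picked after their values were seen. Further genes rose below the 10 largest rises. NSG2, of neuronal endosomes, rose from 0.750 ± 0.184 to 14.6 ± 3.88 FPKM (SD, n = 3; limma adjusted p = 0.000241), and RELN, which encodes the migration signal reelin, from 1.72 ± 0.339 to 16.9 ± 6.84 FPKM (limma adjusted p = 0.00271). The receptor genes RAMP1 and PTGFR rose to 68.6 ± 25.3 and 68.8 ± 15.7 FPKM from 11.1 ± 0.915 and 12.2 ± 1.14 FPKM. Among further falls, MYCBP2, a ubiquitin ligase of growing axons, went from 38.0 ± 1.66 to 14.6 ± 3.06 FPKM (limma adjusted p = 0.00293), the latrophilin gene ADGRL2 from 8.10 ± 0.957 to 1.64 ± 0.747 FPKM and RPRM, a cell cycle inhibitor gene, from 9.71 ± 1.48 to 2.72 ± 1.23 FPKM. DBH, the enzyme that makes noradrenaline, lay below the filter and was not tested, at 0.0837, 0.0499 and 0.0753 FPKM in controls and 1.90, 0.742 and 0.247 in knockouts. TH, another noradrenergic enzyme gene below the filter, overlapped between the groups. It was at 0.282, 0.328 and 0.132 FPKM in controls and 0.215, 0.515 and 0.335 in knockouts.

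MEG8, an imprinted noncoding gene near MEG3, was listed at 0, 0.562 and 0 FPKM in controls and at 4.84, 2.44 and 6.03 in knockouts (limma adjusted p = 0.00601). GSTT1 went from 4.86, 4.93 and 5.13 FPKM to 0, 0 and 0.0177 (limma adjusted p = 3.69e-05), and MGST1 from 3.39, 3.76 and 3.03 FPKM to 0.0884, 0 and 0.

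Knockout 3 lay 46.2% of the way from the controls to the other knockouts on the first component, and its stress response, mitotic and ribosomal genes differed from theirs. Read as a share of control cells mixed into that library, this place would give 53.8%. That figure is rough, because the component is on a log scale and mixing is not. Yet 8 genes nearly silent in knockouts 1 and 2 stood at a median of 0% of the control level in knockout 3 (upper quartile 0.443%). TRIM24 was at its lowest there, at 6.45 FPKM. The estimated depth of knockout 3 was 1.15 times that of knockout 2, which lay furthest from the controls, which argues against low depth as the source. Scaling between libraries left it in place, at 47.1% of the way after quantile normalization. The design gives no group that would separate this library, so no biological explanation was tested, and a difference in culture state or in the cells used may remain.

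A set of 14 genes was at 3 FPKM or more in all libraries of 1 group and at most 5% of that group's lowest value in all of the other, 11 lost in the knockouts (GTSF1, NPY and S100A6 among them) and 3 gained (PAGE1, GSTM1 and the small RNA pseudogene RNU1-70P). Failed estimates at single genes were assumed not to follow the groups, and the other 9 splits of the 6 libraries gave at most 2 such genes. DDX1, listed at 0 in every control and at high values in knockouts 1 and 2, shows that zeros can follow the groups in part. The splits therefore cannot exclude failed estimates. For loss or gain of the chromosome segment around each gene, the flanking genes moved the same way by a median log2 of 0.23 (95% bootstrap interval 0.0878 to 0.405, 13 genes). That median pools all loci, and for 3 of the genes the flanking median was above 0.5, the size predicted for such events. Members of the set were left out of each other's flanks, so neighbours lost together were not counted. Presence and absence of such events therefore cannot be told apart on these few genes, and 3 of the lost genes, ANKRD30A among them, overlap at 1 locus. Whole-gene deletions of GSTM1 and GSTT1 are common in human genomes, and a knockout population grown from few cells, or from another stock, may carry such differences without any action of TRIM24. That was not tested.

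REST fell while members of the neuronal lists rose, and a candidate explanation is release of its targets. A list of 28 genes reported as REST targets, 24 of them tested, shifted upward by a median log2 change of 0.29, with 4 called higher, 0 lower and 21 above 0. Against all other tested genes this gave a limma camera p of 7.79e-05 with the preset correlation. The limma camera p was 0.105 with an estimated correlation, and 13 of the 28 also stand in another list, so this is not independent of the neuronal lists. The call of REST itself ended without any control, without knockout 1 and with no filter on low values (highest limma adjusted p = 0.111), and whether loss of TRIM24 acts on REST was not tested.

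For the count of 1189 genes, 1 of the 10 splits of the libraries into 3 and 3 gave as many, the real one, and the highest other split gave 2. So few splits cannot give a share under 0.05. DDX1, a neighbour of MYCN, was listed at 0 in the 3 controls and knockout 3 and at 10107 and 9542 FPKM in knockouts 1 and 2, and was the single gene at 0 in 1 library and at 1000 FPKM or more in another. All 15 mitochondrially encoded genes of the list were at 0. The entry ENSG00000237973, which the deposited table names hsa-mir-6723, was listed at 4439 ± 228 FPKM in controls and 5432 ± 1474 in knockouts (SD, n = 3). Whether that value comes from a microRNA or from fragments of other genes was not tested.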
